A study of Mus musculus with 2 samples.

How the data were processed

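The series holds 2 single-cell RNA libraries, 1 from female and 1 from male wildtype C57BL/6 mice at 90 days of age. Cells carrying CD45, the surface protein of white blood cells, were enriched with magnetic beads from submandibular glands, one of the paired salivary glands under the lower jaw, per the labels' protocols. Before that step the minced glands were digested in collagenase IV and DNase I with shaking at room temperature. The libraries were made with the 10x Chromium 3' kit of version 3, which tags each captured RNA molecule with a unique molecular identifier (UMI), per the labels' protocols. How many animals entered each library is not given in the sources used here.

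The deposited matrices hold raw counts of UMIs per gene and cell barcode, with no normalization, as the whole numbers and unequal totals in the files show. The submitters' processing notes name Cell Ranger 2.0.2 and 7.1.0 and the mm10 build, without saying which version did what. Whether reads in introns were counted, and how barcodes were called as cells, is not given in the sources used here. The lowest barcode held 894 UMIs in the female and 500 in the male library, so a minimum may have been set before deposit and may have differed between the libraries. Each table lists 32285 genes. Gene positions, spans and biotypes were taken from the GENCODE annotation of GRCm38, the same build as mm10, by Ensembl gene identifier.

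Everything below was computed from those counts with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Barcodes with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. Scrublet, run per library as implemented in scanpy, marked only 5 of 5441 barcodes (0.092%) as doublets. At that share the doublet caller has not worked, so doublets remain among the kept barcodes, and an alternative removed the top 5% of its scores in each library. Kept barcodes of both libraries were scaled to 10000 UMIs, log transformed and clustered together with no batch correction, on 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden algorithm at a resolution of 1. Genes of the sex check, the gland lists and the dissociation list, and mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, took no part in the clustering. Each cluster was named from 19 fixed marker lists by the mean of its scaled marker levels. A name needed a score of at least 0.5 and a margin of at least 0.1 over the next class, both set after the data were seen, and clusters that missed either stayed unnamed. Clusters with under 2000 CPM, UMIs of a gene scaled to a common total, of the nuclear RNA Malat1, a limit also set after the data were seen, are called Malat1-poor. Macrophage-like barcodes were clustered again in the same way at a resolution of 0.6.

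For each library the raw UMIs of a class were summed and divided by their total to give CPM, and the female over male ratio of CPM was taken on the log2 scale. With 1 library per sex there is no test between the sexes and no p-value. Ratios carry 95% conditional Poisson intervals and shares carry 95% Clopper-Pearson intervals. Both cover counting error only, and neither the spread between animals nor that between preparations. A count of 0 was set to 3 UMIs, and a fold against it is a lower bound. For a share of 0, the limit in the text is 3 over the number of barcodes, which is below the upper end of the Clopper-Pearson interval. Genes were counted as apart when their CPM differed at least 2-fold, with at least 20 CPM and 50 UMIs in the higher library.

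For lymphocyte-like barcodes, carried-over macrophage RNA was reckoned for some genes as their macrophage-like CPM times the ratio of C1qa in lymphocyte-like to macrophage-like barcodes, a step added after the data were seen.

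The genes named in the text follow a rule. In macrophage-like barcodes it takes the 12 genes with the highest and the 12 with the lowest ratio, among those with at least 50 CPM and 50 UMIs in the higher library and there at least at the level of pooled lymphocyte-like barcodes. The sex check, gland and dissociation lists and the gene families kept out of the clustering were left out of that ranking. From each fixed list up to 4 members with the largest ratios either way are named, from each macrophage-like subcluster its leading genes, and from other classes with at least 100 barcodes per library the 3 highest and 3 lowest genes under the same limits, against all kept barcodes outside the class. Of the genes these rules take, 4 are not reported here, though they stay in the sums, ranks and list medians. Of 28 fixed gene lists, members with at least 10 CPM in either library count as measured. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins and, in a second comparison added later, on gene span in 10 bins with 5 level bins in each. The 4 list symbols Mx1, Ren2, Smr2l and Ptma-ps1 have no entry in the files, and Aldoa was left out because its symbol stands for more than 1 gene there. The grouping of the samples, the filters, the lists, the markers, the rule for named genes and most alternatives were fixed before the data were examined.

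The counting of genes and the list medians were tested on simulated data drawn from the summed macrophage-like UMIs. For the macrophage-like comparison, over 5810 simulated genes, 0 of 5610 unchanged genes and 0 of 50 set 1.5-fold apart passed the 2-fold limit. All 50 at 3-fold, all 50 at 4-fold and all 50 at 8-fold passed it. The intervals held the true ratio for 95.8% of the unchanged genes and for 94% to 98% of the others. Of 200 simulated lists without a shift, 2.5% fell outside the central 95% of random lists, and of 200 lists shifted by 0.2 on the log2 scale, 100% did. Such draws hold counting error alone, so they say nothing of the spread between animals. Their unchanged genes also share the same true ratio, while real genes do not. In the data, medians of random lists matched on level to the 20 macrophage identity genes spread from -0.44 to 0.14. A shift of 0.2 can stay inside such a spread, so the simulated rates do not carry over to the list percentiles.

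The alternatives covered other barcode filters, doublets, cluster resolution and genes, clustering each library apart, a per-barcode gate on at least 3 of 7 macrophage genes, the median of ratios and CPM without mitochondrial, ribosomal protein, gland and haemoglobin genes as scalings, thinning to 1000 UMIs per barcode, the mean over subclusters and over barcodes, and other gene limits. The mean over subclusters weighs each alike, and within a subcluster a count of 0 was set to 3 UMIs. The smallest subcluster held 26 female and 74 male barcodes, so values in that setting can rest on few UMIs or on that substitute value. Leaving out Malat1-poor clusters, at least 1000 UMIs in both libraries, the top Scrublet scores, immune barcodes as the denominator and the adjustment for gene span were added after the data were seen. No comparison across replicates, with animals as units or of spliced with unspliced RNA was made, and other libraries of the study, if any, were not analysed here.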

Results

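The study profiled the immune cells of the submandibular gland in adult mice of both sexes, and its 2 libraries allow a comparison of resident macrophages, the other immune cells and their genes between a female and a male preparation. The female library held 6704 barcodes and 31342196 UMIs, and the male library 3399 barcodes and 15740386 UMIs. After filtering, 3294 female barcodes (49.1%) and 2142 male barcodes (63.0%) were kept, with medians of 3619 and 2490 UMIs and of 939 and 849 genes. Genes of the gland lists, which code for saliva proteins and epithelial markers, took 27.6% of all UMIs in the female and 13.4% in the male library. Mitochondrial genes took 15.2% and 6.17%. There was 1 library per sex, so no difference given here has a replicate check, and the 95% intervals in brackets cover counting error only.

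The sex of each library was read first. Xist, the noncoding RNA that coats the silenced X chromosome (X 103460366 to 103483254 in mm10), had UMIs in 1477 of 3294 female barcodes (44.8%) and in 95.8% of the female macrophage-like barcodes in Malat1-rich clusters. It had none in 2142 male barcodes, which allows a share of up to 0.140% with a UMI. The Y-linked genes Uty, Eif2s3y and Kdm5d had 0 UMIs in the female library (up to 0.0911% of barcodes) and 1148, 756 and 256 UMIs in the male library. Ddx3y, also on the Y chromosome, had 829 male UMIs in 484 barcodes and 13 female UMIs in 13 barcodes, 12 of which also held Xist. In macrophage-like barcodes Xist was at 793 CPM in the female library, at least 2245-fold higher than in the male. Of the 6 X-linked genes on the list that are known to be read from both X chromosomes, Eif2s3x (log2 female over male 0.82, 0.51 to 1.12) and Pbdc1 (0.66, 0.39 to 0.93) were at least 1.5-fold higher in the female library. Kdm6a and Kdm5c, both histone demethylases, stood at 0.11 and -0.11. The list, which also holds Xist and so has 7 members, had a median of 0.11 that lay at the 96.0th percentile of random lists matched on level. Both libraries carried the sex genes of their labels.

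To compare which cells were recovered, barcodes were grouped by shared markers. Macrophage-like barcodes, marked by the complement genes C1qa and C1qb, Csf1r and Adgre1, made up most of both libraries, with 2100 of 3294 kept barcodes in the female (63.8%, 62.1 to 65.4) and 1827 of 2142 in the male (85.3%, 83.7 to 86.8). With each library clustered apart these shares were 64.8% and 67.8%, and by a per-barcode gate 74.7% and 85.5%, so the size of the gap depends on how the class is drawn. The female library held more barcodes of the gland itself, with gland epithelial-like cells at 10.6% (9.59 to 11.7) against 2.38% (1.78 to 3.12) in the male. The gland epithelial-like shares were 1.54% and 0.628% under the stricter filter and 17.7% and 4.65% without Malat1-poor clusters. An unnamed cluster led by the saliva genes Mucl2, Prol1 and Car6 added 5.95% and 0.607%. Of immune barcodes alone, 78.0% (76.3 to 79.5) of 2694 in the female and 88.5% (87.1 to 89.9) of 2064 in the male library were macrophage-like. The CD45 sort and the filters can set such shares, and epithelial cells should not carry CD45.

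Lymphocytes of the natural killer (NK) and type 1 innate lymphoid (ILC1) kind, which kill target cells and secrete interferon gamma, formed the next class. NK/ILC1-like barcodes were 14.8% (13.5 to 16.2) of the female and 7.56% (6.45 to 8.78) of the male immune barcodes, or 400 and 156 barcodes. A cluster with the granzymes Gzmc and Gzmb and the tissue residency integrins Itgae and Itga1 held 294 female and 102 male barcodes, 10.9% and 4.94% of immune barcodes. A second cluster with Eomes, Gzma and the Ly49 receptor genes Klra4 and Klra8 held 106 and 54, at 3.93% and 2.62%. T cell-like barcodes were few, with 64 and 36 (2.38% and 1.74%), and no order is read from them. Their shares of kept barcodes, 1.94% and 1.68%, went to 0.352% and 0.711% at 1000 UMIs or more and to 3.86% and 4.29% under the stricter filter. Also few were B cell-like (8 and 5) and migratory dendritic-like barcodes (15 and 7), which carry Ccr7 and Fscn1. A cluster with Gata3 and Il1rl1, marks of type 2 innate lymphoid cells (ILC2), had 29 barcodes in the female and 0 in the male library, where 0 of 2064 allows up to 0.145%. Being of 1 library, it may be a trait of that library and not a cell type of females. Median UMIs were 8260 and 10984 in NK/ILC1-like and 2242 and 2110 in macrophage-like barcodes, so a filter on depth acts on these classes unequally. Under the stricter filter the NK/ILC1-like shares of kept barcodes were 19.5% and 13.1%, against 12.1% and 7.28% as reported.

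**Figure D1:**
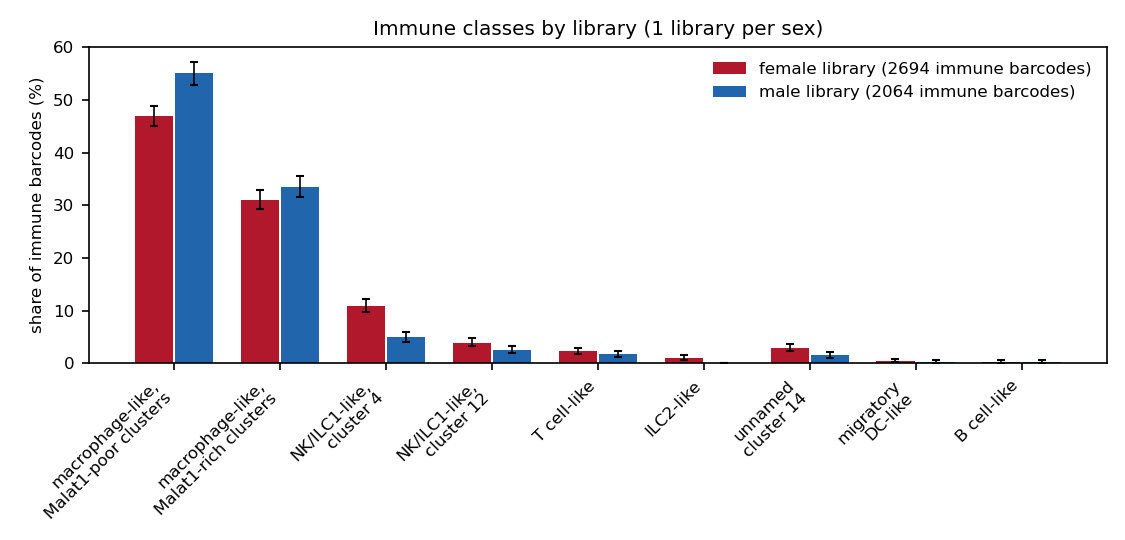
Share of immune barcodes (%) in each immune class for the female library (2694 immune barcodes) and the male library (2064), with bars for the share and lines for its 95% Clopper-Pearson interval, which covers counting error only. NK/ILC1-like cluster 4 stood at 10.9% in the female and 4.94% in the male library, and the ILC2-like cluster at 1.08% and 0.

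The question of whether macrophages take other states in the sexes was addressed by clustering the macrophage-like barcodes again. Most of them, 60.1% (58.0 to 62.3) in the female and 62.1% (59.8 to 64.3) in the male library, lay in clusters poor in the nuclear RNA Malat1, with medians of 1453 and 1316 UMIs against 6466 and 9503 in the Malat1-rich clusters. The 6 subclusters appeared in both libraries. Subcluster 1, with Mir99ahg, Zswim6, Frmpd4, Zfp36l1 and Plxdc2 in the lead, held 34.5% (32.5 to 36.6) of female and 30.8% (28.6 to 32.9) of male macrophage-like barcodes. Subclusters 2 and 3 were Malat1-poor, at 30.2% and 29.1% and at 27.0% and 27.8%. Subcluster 2 was led by the gland transcripts Scgb2b26, Scgb1b27, Wfdc12 and 2310057J18Rik with Nupr1, and subcluster 3 by Ccl5, Lgals3, Bola3, Nme1 and Ftl1. Dividing cells, with Hist1h1b, Top2a, Mki67, Birc5 and Hist1h2ae, made up 4.43% (3.59 to 5.40) and 4.87% (3.93 to 5.96), a difference not detectable at this depth. In the clustering of all barcodes, macrophage-like clusters 10 and 16, led by such genes, held 7.71% (6.61 to 8.94) and 7.06% (5.93 to 8.33), so the order turned within the intervals. Barcodes led by the interferon-induced genes Cxcl10, Ifit3, Ifit2, Rsad2 and Ifit3b stood at 2.57% (1.94 to 3.34) and 3.39% (2.61 to 4.33). In the clustering of all barcodes, macrophage-like clusters 5 and 11, led by such genes, held 15.1% (13.6 to 16.7) and 10.7% (9.29 to 12.2), so the size and order of this group depend on the clustering. A subcluster led by Gm2245, Lysmd4, Gm17231, Insyn2b and Oprm1 stood at 1.24% and 4.05%. No order is read from the last 2 subclusters, since genes that define them also differ between the libraries as a whole. In the clustering of all barcodes, the Malat1-rich clusters that held most cells differed. Cluster 3 held 535 of 837 female and 190 of 692 male barcodes and cluster 6 held 59 and 248. Cluster 3 was led by the inflammatory and stress genes Cxcl2, Ccl3, Il1b and Hspa1a, with Il1a and Egr1 also among its leading genes. Cluster 6 was led by Plxna4, Plxdc2, Nfkbiz and Cacnb2, and Il1a was highest there, at 322 CPM. The reclustering did not show this split, as subcluster 1 held 80.7% of female and 71.4% of male barcodes in Malat1-rich subclusters. No difference in states is read from it, since most of these genes could help to define the clusters and no batch correction was made. Hspa1a and Egr1, of the dissociation list, took no part in the clustering. Save for Hspa1a, the values of these leading genes below cannot be told apart from the balance of these clusters. Within clusters 3 and 6, 5 heat shock genes that include Hspa1a had median log2 ratios of 1.855 and 2.11.

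Female macrophage-like barcodes held more of the tetraspanin Cd9, the glucocorticoid receptor co-chaperone Fkbp5, the heme oxygenase Hmox1, lysozyme (Lyz2), galectin-3 (Lgals3) and heat shock genes. Male macrophage-like barcodes held more of the cytokine Il1a, the NF-kB cofactor Nfkbiz, the plexin Plxna4 and the calcium channel subunit Cacnb2. Of 6023 genes at the set level, summed from 8080040 female and 8486526 male UMIs, 30 were at least 2-fold higher in the female and 145 in the male library. The 30 included 6 gland genes, 5 of the dissociation list and 2 of the sex check, and the 145 included 8 gland genes and 4 of the sex check. That balance depends on the scaling. The median gene stood at a log2 ratio of -0.30, and with that median set to 0 the counts were 45 and 28, so that the female share of genes apart went from 17.1% to 61.6%. Over 8569 genes with at least 50 UMIs in both libraries, the median was -0.27, and the ratios below are best read against it. The genes higher in the male library also had longer spans, with a median of 84.8 kb against 7.29 kb for those higher in the female and 30.4 kb for all. Malat1-rich clusters alone gave 38 and 104 genes of 6353, and a per-barcode gate on macrophage genes gave 158 and 137. That gate can also admit other cells that hold macrophage RNA. C1qa, 1 of its genes, had UMIs in 58.1% of female and 41.6% of male lymphocyte-like barcodes.

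Among the 12 genes with the highest female ratio, Cd9 (6: 125460266 to 125494791) stood at 169 CPM in the female and 54.3 CPM in the male library, a log2 ratio of 1.64 (1.49 to 1.80). Cd9 was highest of all in gland epithelial-like cells, at 876 CPM in their cluster 18, while lymphocyte-like barcodes held 131 and 102 CPM. Fkbp5 (17: 28399094 to 28517527), a gene induced by glucocorticoids, stood at 281 and 106 CPM (1.41, 1.29 to 1.52), and its ratio in lymphocyte-like barcodes was 0.24. Bag3 (7: 128523616 to 128546981), which couples Hsp70 to protein breakdown, had a ratio of 1.75 (1.52 to 1.99), and of -0.18 in lymphocyte-like barcodes. As a mean over subclusters, Fkbp5 stood at 0.66 and Bag3 at 0.43. Hmox1 (8: 75093621 to 75100589), which breaks down heme, stood at 61.8 and 28.4 CPM (1.12, 0.90 to 1.35). Lyz2 (10: 117277331 to 117282321) stood at 2046 and 1065 CPM (0.94), Lgals3 (14: 47367751 to 47386160) at 354 and 196 CPM (0.85) and the methionine sulfoxide reductase Msrb1 at 67.1 and 41.1 CPM (0.71). In lymphocyte-like barcodes the ratio was 3.47 for Hmox1, from 67 and 3 UMIs, 2.21 for Lyz2 and 1.17 for Lgals3. C1qa stood there at 20.5% of its macrophage-like level in the female and 7.77% in the male library. Macrophage RNA carried over at those shares would bring 92.9% of the female UMIs of Hmox1, 73.2% of those of Lyz2 and 22.8% of those of Lgals3, so the ratios of Hmox1 and Lyz2 there are not read as those of lymphocytes. The reckoning is rough, since for Hmox1 in the male library it gives 5.38 UMIs where 3 were found. The noncoding gene G530011O06Rik, placed at X: 169975043 to 169978917, had a ratio of 1.28. Its ratio was 3.01 in lymphocyte-like barcodes, where carried-over RNA would bring more UMIs than were found. Gm42418, a noncoding gene that overlaps a ribosomal RNA repeat, had a ratio of 0.91. The remaining genes of the 12 were gland transcripts. Fxyd2, a subunit of the sodium pump (2.52), and the secretoglobins Scgb2b26 (2.22) and Scgb1b27 (1.26) were highest in gland epithelial-like clusters and had like ratios of 2.87, 2.51 and 1.34 in lymphocyte-like barcodes.

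Among the 12 genes with the lowest ratio, Cacnb2 (2: 14603088 to 14987908) was 5.24-fold higher in the male library, at 78.5 CPM there, a log2 ratio of -2.39 (-2.68 to -2.11). Il1a (2: 129299610 to 129309972), an alarm cytokine of the interleukin 1 family, stood at 108 and 251 CPM (-1.22, -1.33 to -1.10), and Nfkbiz (16: 55811375 to 55838899), which steers NF-kB target genes, at 232 and 534 CPM (-1.20, -1.28 to -1.12). Plxna4, a semaphorin receptor, had a ratio of -1.45, Ms4a14 of -1.25, the endosomal proton exchanger Slc9a9 of -1.21, and the X-linked Arhgap6 of -1.24. The Notch coactivator Maml3 had a ratio of -1.13. As a mean over subclusters, Il1a stood at -0.45 and Cacnb2 at -1.41, and Ms4a14 stood at -0.50 with barcodes thinned. With the median of genes of like span and level taken off, Cacnb2 stood at -1.74, Il1a at -1.28, Ms4a14 at -1.24, Nfkbiz at -1.02 and Plxna4 at -0.72, while Arhgap6, Slc9a9 and Maml3 lay between -0.52 and -0.40. The last pair, 2310057J18Rik (-7.10) and the protease inhibitor gene Wfdc12 (-2.28), were gland transcripts with ratios of -6.96 and -2.17 in lymphocyte-like barcodes.

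**Figure D2:**
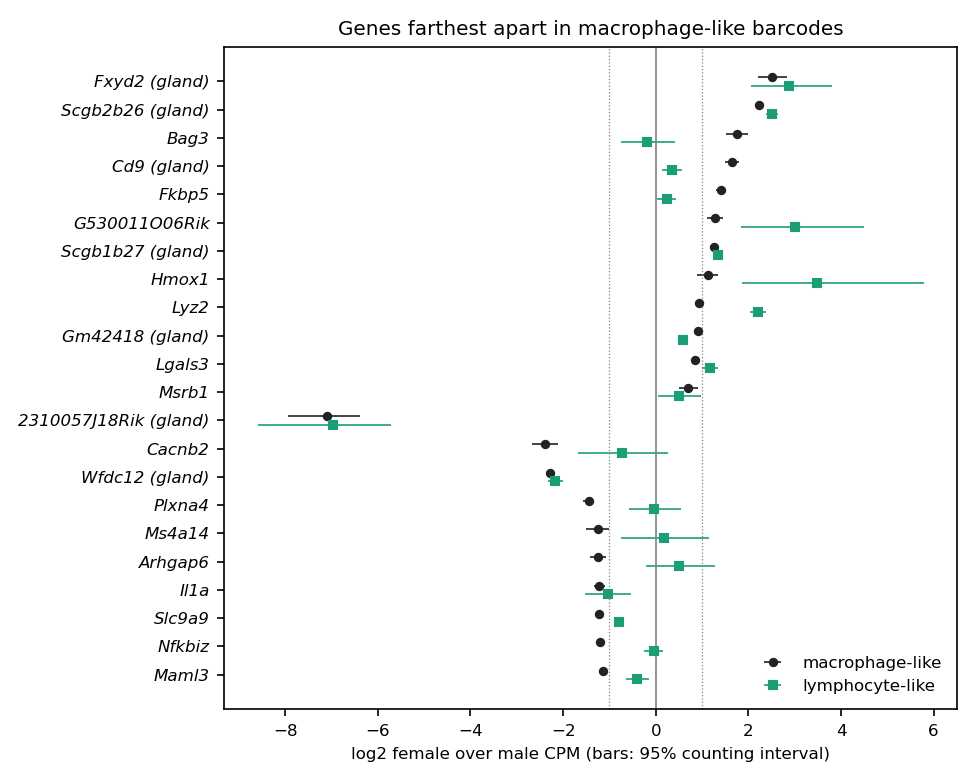
Log2 ratio of female over male CPM of the reported genes among the 12 with the highest and the 12 with the lowest ratio in macrophage-like barcodes (circles), beside the ratio in lymphocyte-like barcodes (squares), with lines for 95% counting intervals and dotted lines at 2-fold. Genes marked as gland are highest in a gland epithelial-like cluster. Cd9 stood at 1.64 in macrophage-like and 0.36 in lymphocyte-like barcodes, while 2310057J18Rik stood at -7.10 and -6.96.

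Genes of lipid-associated macrophages, a state described in fat and injured tissue, stood higher in the female library as a group. The median ratio of 17 measured members was 0.55, above 100% of random lists, with 8 members at least 1.5-fold higher in the female and 1 in the male library. Beside Cd9, the matrix protein gene Spp1 (31.9 and 13.1 CPM, 1.29) and the fatty acid carrier Fabp5 (1.17) were higher in the female library, and the elastase Mmp12 (-1.09) was higher in the male. The list's median in lymphocyte-like barcodes was 0.92, to which carried-over macrophage RNA adds. At the share of C1qa it would bring 92.3% of the female UMIs of Apoe, which stood at 1.76 there. For Spp1 (2.365 there), Fabp5 (1.145) and Cd9 (0.36) it would bring 38.8%, 29.5% and 26.6%. Whether the shift of the list is particular to macrophage-like barcodes thus stays open. Of 24 lysosome genes, with a median of 0.03 at the 92.6th percentile (87.1th with span), Ctsd (0.64) and Cd63 (0.62) were at least 1.5-fold higher in the female library. Tfeb, the main regulator of lysosome genes, stood at -0.47 and the cholesterol carrier Npc2 at 0.40. The 11 iron genes had a median of 0.01 (92.0th percentile, 76.4th with span). Hmox1 was higher in the female library, Ireb2, which controls iron uptake, stood at -0.72, the prostaglandin synthase Hpgds at -0.58 and the ferritin chain Fth1 at 0.49.

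Of 20 measured genes of the NF-kB response, 7 were at least 1.5-fold higher in the male and 0 in the female library, with a median of -0.33. The list lay at the 25.5th percentile of lists matched on level alone and at the 0.05th percentile of lists matched on level and span. The median random list stood at -0.24 and 0.04 in these comparisons. As a mean over subclusters, which weighs small and large ones alike, the list's median was -0.03, and in lymphocyte-like barcodes it was 0.15. Immediate early genes, which tissue handling induces, moved the same way in macrophage-like barcodes, with a median of -0.42 and 14 of 15 below 0. Beside Il1a and Nfkbiz its members farthest apart were the chemokine Ccl7 (-1.20) and the NF-kB subunit Nfkb1 (-0.80), which came to -0.36 and -0.23 under the alternatives nearest to 0. The 19 chemokines and receptors went both ways, with Ccl7 and the receptor Ccr1 (-0.85) higher in the male library and the interferon gamma-induced Cxcl9 (38.2 and 17.6 CPM, 1.12) and Cxcr4 (0.87) higher in the female, which came to 0.58 and 0.32 under the alternatives nearest to 0. Their median of -0.11 lay at the 84.9th percentile by level and at the 5.18th with span matched. The 8 genes of alternative activation had a median of -0.27 (55.7th percentile, 17.4th with span), with Socs3 (60.2 and 141 CPM, -1.22) and the mannose receptor Mrc1 (-1.12, and -0.44 by the per-barcode gate) at least 1.5-fold higher in the male library, Stat6 at -0.43 and Pparg at -0.28. Mrc1 was higher outside the class, at 1189 and 1682 CPM in parts of unnamed cluster 14.

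Genes that mark macrophages in general went both ways. The 20 identity genes had a median of 0.13 (96.9th percentile, 97.1th with span), with Lyz2 higher in the female library, the F4/80 gene Adgre1 (-0.72, and -0.02 with gene span and level taken off) in the male, Cx3cr1 at -0.57, Sirpa at -0.56 and Trem2 at 0.55. The CD11c or CX3CR1 interstitial list of 17 genes had a median of -0.32 at the 33.7th percentile, and at the 0.935th with span matched. Mmp12, Mmp13 (-1.07) and the purine receptor P2ry12 (-1.03) were higher in the male library and Cd9 in the female. Of 9 perivascular resident genes, with a median of -0.26 (66.8th percentile, 30.9th with span), Igf1 (11.8 and 3.06 CPM, 1.94) was higher in the female library, Mrc1 and Stab1 (-0.61) in the male, and Wwp1 stood at -0.52. Of 9 monocyte-derived genes, with a median of 0.04 (95.4th percentile, 87.0th with span), S100a4 (1.05), Lyz2 and S100a6 (0.70) were at least 1.5-fold higher in the female library, and Itgal stood at -0.27. S100a4 and S100a6 are low in macrophage-like barcodes and stood at 655 and 366 CPM and at 979 and 841 CPM in lymphocyte-like barcodes. The ratio of S100a4 was 3.29 without the top Scrublet scores, and that of S100a6 was 0.21 as a mean over barcodes. The 13 genes that take up dead cells and lipids had a median of -0.51. Itgav (-0.89), the cholesterol exporter Abca1 (-0.88), Elmo1 (-0.84) and the lipoprotein receptor Scarb1 (-0.73) were among 6 at least 1.5-fold higher in the male library, yet the list lay at the 5.64th percentile by level and at the 64.3th with span matched.

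Antigen presentation genes lay close to equal levels as groups. The 12 genes of MHC class II presentation, the main list for this question, had a median of -0.05 at the 73.5th percentile (51.2th with span). The alternatives put it between -0.26 and 0.22. Its sign turned under both other scalings, under the stricter filter, without Malat1-poor clusters and as a mean over subclusters. Their activator Ciita (89.1 and 175 CPM, -0.98) and the costimulator Cd86 (-0.62) were at least 1.5-fold higher in the male library, H2-Ob stood at -0.38 and Cd40 at -0.36, which turned to 0.29 and 0.40 as means over subclusters, while H2-Aa and Cd74 stood at 0.27 and 0.16. The 11 genes of MHC class I had a median of 0.18 (98.2th percentile by level, 75.4th with span), with H2-Q7 (0.67) higher in the female library, Nlrc5 at -0.56, H2-D1 at 0.34 and Psmb8 at 0.32. The 25 type I interferon genes had a median of 0.23, at the 100th percentile by level and the 99.97th with span. Their median in lymphocyte-like barcodes was 0.64. Carried-over macrophage RNA can add to it, since the macrophage identity list stood at 1.365 there and the carried-over part was not reckoned for interferon genes. Whether the shift is particular to macrophage-like barcodes thus stays open. Only Bst2, which tethers viruses (1150 and 725 CPM, 0.67), was at least 1.5-fold higher in the female library, Ifit2 stood at 0.48, Slfn8 at -0.50 and Stat2 at -0.47. The 10 complement genes had a median of -0.17 (63.0th percentile, 35.1th with span) and none was 1.5-fold apart. C5ar2 stood at -0.50, Itgb2 at -0.38 and C1qa at 0.30.

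Of hormone-linked genes, the estrogen receptor gene Esr1 was low in both libraries, at 3.96 CPM in the female and 16.9 CPM in the male (-2.09, -2.69 to -1.53), from 32 and 143 UMIs, and its ratio was -0.96 as a mean over subclusters. The glucocorticoid receptor gene Nr3c1 stood at 155 and 252 CPM (-0.71). The 7 measured receptor and steroid enzyme genes had a median of -0.25 (57.5th percentile, 66.5th with span), with Hsd17b4 at -0.31 and Hsd17b11 at -0.25. The 13 genes that respond to glucocorticoids or androgens had a median of 0.10 at the 99.1th percentile (98.8th with span). Fkbp5 and Ddit4, a brake on mTOR signalling (31.2 and 11.8 CPM, 1.40), were higher in the female library, the decoy receptor gene Il1r2 (-0.66) in the male, and the kinase gene Sgk1 stood at 0.42. Of 10 growth factor and repair genes, with a median of -0.33 (48.6th percentile, 21.5th with span), Igf1 was higher in the female library, Fgf2 (-0.99) and Pdgfb (-0.68) in the male, and Tgfb1 stood at -0.55.

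Metabolic genes and the cell cycle had medians whose sign moved with the settings. The 40 genes of oxidative phosphorylation had a median of 0.13, at the 100th percentile by level and the 46.1th with span, and none was 1.5-fold apart. Atp5d, Ndufb8, Cox5a and Atp5o stood between 0.44 and 0.50. The 19 glycolysis and hypoxia genes had a median of 0.06 (99.5th percentile, 99.6th with span), with Hk2 (-0.77) and Bnip3 (-0.72) higher in the male library, Pfkp at 0.56 and Hk1 at -0.46, which turned to 0.54 as a mean over subclusters. The 10 genes of cholesterol and fatty acid synthesis had a median of -0.22 (71.5th percentile, 80.7th with span), with Srebf2 (-0.68) and Acaca (-0.67) higher in the male library, though at -0.17 and -0.03 with gene span and level taken off, Insig1 at -0.51 and Fdps at 0.46. The 19 cell cycle genes had a median of 0.08 (99.8th percentile, 94.1th with span), with the histone gene Hist1h2ap (0.87) higher in the female library, Stmn1 at 0.46, Mcm3 at -0.39 and Ccnb2 at -0.37. The medians for oxidative phosphorylation, glycolysis and the cell cycle turned below 0 with barcodes thinned to 1000 UMIs, at -0.04, -0.09 and -0.32, and so did the ratio of Hist1h2ap, at -0.32. In Malat1-rich clusters alone the cell cycle list stood at 0.47. The ratio of Bnip3 turned to 0.16 as a mean over subclusters.

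**Figure D3:**
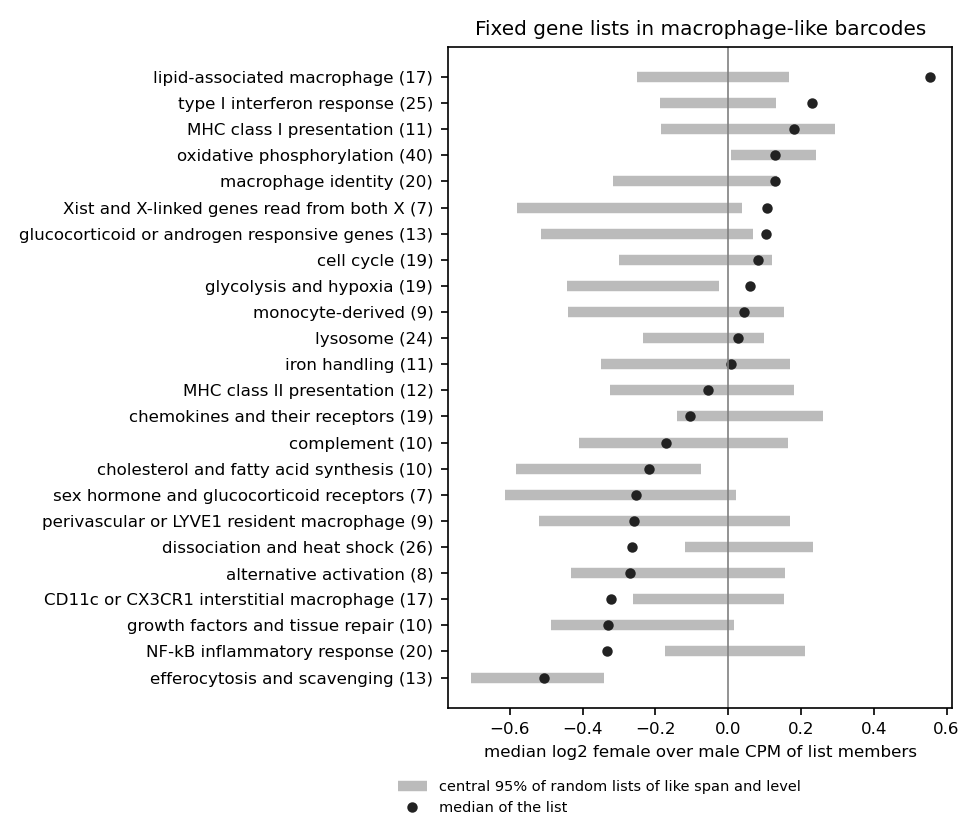
Median log2 ratio of female over male CPM of each fixed gene list in macrophage-like barcodes (points, with the number of measured members in brackets after the name), beside the central 95% of medians of 10000 random lists matched on gene span and level (grey bars). The lipid-associated list at 0.55 and the interferon list at 0.23 lay above their bars, and the NF-kB list at -0.33 and the dissociation list at -0.26 below theirs.

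Stress genes and gland transcripts also differed. Of 26 genes of the dissociation and heat shock list, with a median of -0.26 (26.9th percentile, 0.01th with span), the chaperone genes Hspa1b (207 and 36.1 CPM, 2.52), Hsph1 (2.04), Hspa1a (440 and 146 CPM, 1.59), Dnaja1 (1.25) and Dnajb1 (1.05) were at least 1.5-fold higher in the female library. Another 6 were at least 1.5-fold higher in the male library, among them Socs3 and Egr1 (-0.97). Mucl2, the most abundant gland transcript, took 68590 CPM in female and 24510 CPM in male macrophage-like barcodes and 35840 and 11260 CPM in lymphocyte-like barcodes. The kallikrein Klk1 stood at 521 and 15.8 CPM (5.04) in macrophage-like and at 197 and 6.15 CPM (5.00) in lymphocyte-like barcodes. The 8 other gland epithelial genes, among them Oit1 (2.45), Prol1 (1.98) and A630073D07Rik (1.66), had a median of 1.41 and all 8 were at least 1.5-fold higher in the female library. Of 15 male-biased gland genes, 12 were at least 1.5-fold higher in the male library, with Klk1b16 at -2.88 and Klk1b8 at -2.80, and 2 in the female, with a median of -1.69. Smgc, the single measured gene of the female-biased list, had 75.5 CPM in the female and 0 in the male library, at least 214-fold higher. Since cells of different lineages share these ratios, gland transcripts are not reported as macrophage genes.

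Of 80 reported genes at least 1.5-fold apart in macrophage-like barcodes, 37 were so under all alternatives run for them. The values nearest to 0 of the others are given above or here. With gene span and level taken off, Abca1 stood at -0.19, Cd86 at -0.22, Ciita at -0.58, Elmo1 at -0.15, Fgf2 at -0.47 and Hk2 at -0.37. Ireb2 stood at -0.20, Itgav at -0.32, Nr3c1 at -0.14 and Scarb1 at -0.27 in that setting. As a mean over subclusters, Cd63 stood at 0.31, Ctsd at 0.37 and Mmp13 at -0.36. By the median of ratios, Ccr1 stood at -0.58, Pdgfb at -0.41 and Stab1 at -0.33. By the per-barcode gate, Il1r2 stood at -0.11, Msrb1 at 0.52, Mucl2 at 0.36, Oit1 at 0.41, Scgb1b27 at 0.09 and A630073D07Rik at 0.13. With barcodes thinned, Bst2 stood at 0.39, Eif2s3x at 0.50 and Pbdc1 at 0.45, and as a mean over barcodes H2-Q7 stood at 0.40.

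In NK/ILC1-like cells, the other class with over 100 barcodes per library, the granzyme gene Gzmc stood at 1865 CPM in the female and 696 CPM in the male library, a log2 ratio of 1.42 (1.34 to 1.51). The calcium-binding S100a4 stood at 604 and 249 CPM (1.28, 1.14 to 1.42) and Lgals3 at 349 and 155 CPM (1.17). Lgals3 is also abundant in macrophages, and C1qa, a macrophage gene that lymphocytes should lack, stood at 1381 CPM in female and 424 CPM in male lymphocyte-like barcodes. Higher in the male library were the transcription factor gene Ikzf2 (24.1 and 74.2 CPM, -1.62, -2.00 to -1.24), the DNA polymerase gene Poln (-1.91) and Hivep1 (-1.52). Under the stricter filter Ikzf2 stood at -0.61, less than 2-fold apart, and Gzmc at 2.13. The balance of the NK/ILC1-like clusters, given above, enters each of these values. Genes spanning at least 100 kb stood higher in the male library in lymphocyte-like barcodes too, with a median of -0.49, and gene span was not taken off here. Over all lymphocyte-like barcodes, 131 genes of 6800 were at least 2-fold higher in the female and 145 in the male library. With their median log2 ratio of -0.22 set to 0 the counts were 206 and 61, so no balance between the sexes is read from them.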

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

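The comparison of macrophage-like with lymphocyte-like barcodes, the reckoning of carried-over RNA and the look at barcodes left out by the filters were chosen after the data were seen, and none of the differences in this part was tested. Each gene given first has list-member ratios with opposite signs in the 2 classes and counting intervals on either side of 0.

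In lymphocyte-like barcodes the mannose receptor gene Mrc1 had a log2 ratio of female over male of 2.69 (52 and 4 UMIs), against -1.12 in macrophage-like barcodes. Scarb1 stood at 1.69 (26 and 4 UMIs) against -0.73, and the chemokine receptor gene Ccr1 at 1.17 (50 and 11 UMIs) against -0.85. The decoy receptor gene Il1r2 stood at 4.80 (2.26 to 10.1, from 56 and 1 UMIs) against -0.66. Cxcl9 went the other way, at -1.65 in lymphocyte-like barcodes (18 and 28 UMIs) against 1.12. Macrophage RNA lay in lymphocyte-like barcodes too, with C1qa at 20.5% of its macrophage-like level in the female and 7.77% in the male library. At those shares it would bring 47.3 of the female UMIs of Ccr1, 12.2 of those of Scarb1, 13.3 of those of Mrc1 and 10.4 of those of Il1r2. It would also bring 38.5 female UMIs of Cxcl9, more than were found, and 16.01 male UMIs of Ccr1, 5.47 of Mrc1 and 3.08 of Il1r2, again more than were found. The reckoning is thus rough and leaves out RNA from the Mrc1-rich unnamed barcodes, so none of these ratios is read as one of lymphocytes.

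The 3409 female and 1253 male barcodes left out by the filters also carried gland transcripts. Smgc, a gene of female-biased gland secretion, stood at 158.9 CPM in the female barcodes left out, with 0 of 2025859 UMIs in the male ones. The gland transcript 2310057J18Rik stood at 2308 CPM in the male barcodes left out and at 9.27 CPM in the female ones.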

How the results depend on the processing

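The macrophage-like share was lower and the NK/ILC1-like share higher in the female library under every alternative run for them. Of 1521 values of 117 reported genes in macrophage-like barcodes, 995 stayed within the counting interval, 524 moved and 2 reversed, and for 26 lists 358 of 389 stayed within the spread of random lists, 23 moved and 8 reversed. For the 6 NK/ILC1-like genes, 35 of 48 stayed and 13 moved. Reversed means a turned sign in a gene at least 1.5-fold apart or a list outside the central 95% of random lists. A sign turned at all in 32 values of 17 genes and in 40 values of 16 lists. Of 80 genes at least 1.5-fold apart as reported, 37 were so under all alternatives run for them. No paired analysis was possible because there was 1 library per sex. The top Scrublet scores, 1000 UMIs, Malat1-poor clusters, immune denominator and gene span alternatives were chosen after the data were seen. For values that moved or reversed the cause was not tested, except that a smaller denominator and other limits on CPM and fold change the number counted by construction.

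The macrophage-like share (63.8% female, 85.3% male) was 60.3% in the female library under the looser filter, 57.8% and 77.7% under the stricter one and 66.2% (female) without the top 5% of Scrublet scores. It was 46.4% and 70.0% without Malat1-poor clusters, 78.0% and 88.5% of immune barcodes, 64.8% and 67.8% with each library clustered apart and 74.7% (female) by the per-barcode gate. The NK/ILC1-like share (12.1% and 7.28%) was 9.46% and 5.61% under the looser and 19.5% and 13.1% under the stricter filter. It was 22.2% and 15.8% without Malat1-poor clusters. In the female library it was 10.8% at 1000 UMIs or more, 10.7% without the top Scrublet scores, 14.8% of immune barcodes and 10.8% at a resolution of 2. The gland epithelial-like share went to 1.54% and 0.628% under the stricter filter, and the T cell-like share to 0.352% and 0.711% at 1000 UMIs or more and to 3.86% and 4.29% under the stricter filter, where its order turned in both. The ILC2-like cluster was not recovered under the looser filter.

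Genes at least 2-fold higher in the male library (145) numbered 95 under the stricter filter, 32 by median of ratios, 80 by CPM without mitochondrial, ribosomal, gland and haemoglobin genes, 65 as a mean over barcodes and 41 with gene span and level taken off. Those higher in the female library (30) numbered 158 by the gate, which can also admit other cells that hold macrophage RNA. With at least 100 CPM there were 14 and 43, with 5 CPM 66 and 346, and at 1.5-fold 82 and 1483.

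At double the subcluster resolution, Malat1-poor subclusters held 60.9% and 62.3% (57.2% and 56.9% as reported), and the interferon subcluster 1.90% and 1.64%, where the order turned. It was not recovered at the lower resolution.

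The cell cycle list turned to -0.22 under the gate, -0.32 thinned to 1000 UMIs and -0.29 as a mean over barcodes. Oxidative phosphorylation turned to -0.035 thinned, -0.073 as a mean over barcodes and -0.013 with span and level taken off, and glycolysis to -0.087 thinned and -0.15 as a mean over barcodes. Hist1h2ap turned to -0.32 thinned and Bnip3 to 0.16 as a mean over subclusters. The lipid-associated list stayed between 0.37 and 0.83, the NF-kB list between -0.47 and -0.03 (the latter as a mean over subclusters) and Cd9 between 1.48 and 1.91 over the alternatives run. Thinning kept 1972 of 2100 female and 1534 of 1827 male macrophage-like barcodes.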

Other observations

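Chosen after the result was seen were the free RNA test and both tests of dying cells for Malat1-poor barcodes, the tests of the short and the long named genes apart, and the test of immediate early genes.

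Some myeloid barcodes met no single marker list and stayed unnamed, 78 female and 33 male barcodes in cluster 14, or 2.90% and 1.60% of immune barcodes. Its parts had different leading genes. A part of 43 barcodes (22 female and 21 male) held Mrc1 at 1189 CPM. Its leading genes included Cd209f, Cbr2 and Folr2, of the perivascular macrophage list, and Acp5. The gland transcripts 2310057J18Rik, Klk1, Wfdc12 and Klk1b26 were also among them. A part of 30 barcodes (25 and 5) was led by Mir99ahg and Mertk and held Mrc1 at 1682 CPM. A part of 25 barcodes (19 and 6) was led by S100a8 and S100a9, genes of neutrophils and monocytes, and one of 9 (8 and 1) by Retnla and Fn1. The last 4 barcodes, all female, were led by Ly6d and held Siglech, genes of plasmacytoid dendritic cells. No order between the sexes is read from parts this small.

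Gland epithelial-like barcodes, 350 female and 51 male, held the saliva gene Mucl2 at 401800 and 441600 CPM. The class lay in different clusters per library, with 231 female and 14 male barcodes in cluster 7, led by kallikreins, and 89 and 32 in cluster 13, so its ratios carry that balance. Klk1 stood at 9802 and 461 CPM in the class, a log2 ratio of 4.41, but at 6.92 in cluster 7 and -1.40 in cluster 13, and Smgc at 18185 and 1 UMIs (12.65, 10.17 to 17.95). Higher in the male library were Wfdc12 (-3.83) and 2310057J18Rik (-9.94), also within clusters 7 and 13. Klk1b22, of the male-biased list, stood at 193 and 21.9 CPM (3.14), but at 0.85 within cluster 7 and, from 8 UMIs each, at -1.37 (-2.98 to 0.24) within cluster 13. Egf stood at 25.8 and 23.7 CPM (0.12, -0.34 to 0.60). In the barcodes left out by the filters, Egf stood at 36.1 CPM in the female and 729 CPM in the male library and Wfdc12 at 589.7 and 7315 CPM.

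Most macrophage-like barcodes in both libraries were poor in Malat1. Free RNA in empty droplets was argued against, since the median such barcode held 105 female and 108 male UMIs of C1qa, C1qb, C1qc, Apoe and Cd74, against 23 and 3 in lymphocyte-like barcodes, at least 4.57 times as many, at a like load of gland UMIs (229 against 216 and 121 against 126), which took no part in the clustering. The naming favours this test, since C1qa, C1qb, C1qc and Apoe are among the markers that named these clusters, so its weight lies in the like gland load. The gland UMIs counted are those of the gland lists. Gland transcripts outside these lists, such as Scgb1b27 and Wfdc12, were not kept out of the clustering, so that load is not wholly independent of it. Dying cells that kept their nucleus were argued against by the low Malat1 that defines these clusters and, restating it in part, by genes of at least 100 kb, whose median log2 ratio of Malat1-poor over Malat1-rich was -3.19 in the female and -3.47 in the male library. Cell parts without a nucleus may be the source, though the choice by Malat1 favours this test too, as the gap between long genes and those under 10 kb was at least as wide as -3.28. Dying cells that kept mitochondria stay open, with a mitochondrial share higher by at least 0.467 points, and a part played by sex was not tested.

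Genes with long spans stood higher in the male macrophage-like barcodes, with medians of -0.66 for those of at least 100 kb and 0.13 for those under 10 kb. Named male-higher genes under 30 kb numbered 5, 2 of them gland transcripts, and genes of like span and level had medians from -0.18 to 0.19. The trend with span thus accounts for little of their ratios. With these medians taken off, 5 of 5 stayed at least 1.5-fold higher in the male library. That count decides nothing, since the genes were picked for ratios of -1.20 or lower, which such medians cannot bring under 1.5-fold. Of 7 named genes of at least 100 kb, 2 stayed so, Cacnb2 and Plxna4. Over all 12 the count was 7, between the bounds set for it, which leaves open how many of the 12 span sets. A library-wide difference in nuclear RNA may account for the trend, as Spearman's rho across genes of span and ratio was -0.48 in lymphocyte-like barcodes too, though genes are not independent replicates. Whether sex, the preparation or a difference in the counting of intron reads, which the sources do not rule out, sets it stays open and untested.

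Of the dissociation list, 5 heat shock genes picked because they stood higher in female macrophage-like barcodes had a median log2 ratio of 1.59. A dissociation response of immediate early genes was argued against, as their median was -0.42 and 14 of 15 lay below 0. The balance of clusters was argued against by a mean within Malat1-rich clusters of 1.67. A stress response of the whole female library may account for it. The median was 1.455 in lymphocyte-like barcodes without C1q UMIs, from 168 female and 70 male barcodes. There Dnaja1, with 584 and 275 UMIs, stood at 0.43, and the other genes of the 5 stood between 1.13 and 5.01. Bag3, which couples Hsp70 to protein breakdown, is outside the 5. It stood at -0.18 (-0.75 to 0.41) in all lymphocyte-like barcodes, against 1.75 in macrophage-like ones, and so did not share the shift. For the 5 genes the median was 0.97 in gland epithelial-like barcodes. It was -1.81 in endothelial-like barcodes, where 4 male barcodes held 0 UMIs of these genes and 35 female ones 144, so that value rests on the floor. Handling and sex cannot be separated with 1 library each, and sex as the source was not tested.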
